A study of Mus musculus with 12 samples.

How the data were processed

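Heart RNA was sequenced in 12 libraries from female FVB mice, 3 in each of 4 groups. Mice received water, sunitinib at 40 mg/kg/day, sorafenib at 30 mg/kg/day or erlotinib at 50 mg/kg/day for 14 days. Per the labels, total RNA was extracted with an RNeasy kit and its polyA fraction was made into stranded libraries with a KAPA kit. The series also concerns the kinome, and only the RNA-seq data were used here.

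The submitters' notes name RSEM, Picard 1.88, SAMtools 1.2 and the mouse genome build mm9. The aligner, the RSEM version and the annotation release are not given in the sources used here. The authors deposited, for each library, RSEM expected counts per gene, which are estimated read counts that can be fractional where a read fits more than 1 gene. In them, 89.5% to 90.3% of the values were exactly whole, genes at 0 included. The deposited TPM values (which also divide by transcript length) summed, per library, to 54.9% to 60.8% of what a full set of genes gives. The listed genes were therefore part of a larger set, so the column totals are not the full sequencing depth. The authors also deposited a scaled signal per gene and library, which is the expected count times 1 factor per library. It set the 75th percentile of the values above 0 to between 998 and 1000, and the same values stood in the table for the whole series. Neither scaling removes a difference in composition between libraries. TPM was used only to check the files.

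Expected counts of 21705 genes were rounded and filtered with filterByExpr of edgeR, which left 13440 genes. The totals ran from 14.3 to 16.5 M expected counts (M, 1e+06) per library. TMM factors were between 0.949 and 1.04. A quasi-likelihood model of edgeR 4.0.16 (robust, R 4.3.3) was fitted to all 12 libraries with 1 coefficient per group, and the 6 comparisons between groups were read from it. A test of any difference among the 4 groups was read from the same model. Benjamini-Hochberg adjusted p under 0.05 was called as passing. Levels are TMM-normalised CPM, given as mean ± SD over 3 libraries, and fold changes are given on the log2 scale ± SE of the fit. The biological coefficient of variation was 0.128. Tests were two-sided.

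In all, 62 gene lists were written before the data were examined, together with the comparisons, the rule for named genes and the alternatives. The lists cover drug targets and their signalling, heart muscle function, metabolism, stress responses, clock genes, cell types of the heart, and other tissues that a dissection could carry over. Lists with at least 5 tested members, 55 in all, were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between members. Adjusted p values over the 55 lists are given beside those with a correlation estimated for each list. A list score is the mean over its members of log2 CPM minus the member's mean over all libraries.

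Named genes were chosen as follows. For each drug against control, the 10 largest rises and 10 largest falls were taken among genes that passed, averaged at least 1 CPM and had no overlap between the groups. Where fewer than 5 passed, the 10 of smallest p were taken and are reported as not passing. The 3 members of smallest p from the 5 lists of smallest p, and 16 fixed genes, were added. For drug against drug, the 5 largest differences each way were taken. Predicted or unnamed gene models were skipped, and some genes that the rule took are not used here. Members of other lists are named as examples of a count, smallest p first, and genes chosen after their values were seen are marked so. Symbols are those of the files. A current symbol, found by Entrez ID for 13398 of the 13440 tested genes, is added where it matters. The annotation at hand was for another build than the authors used, so no positions are given.

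The model was tested on simulated data with the same depth and the same spread per gene, in which genes varied independently. For each drug, 98 or 99 tested genes were changed at 1.5-fold and as many at 2-fold, all at once. Of genes given a change of 2-fold, 71.4% were recovered for sunitinib, 76.8% for sorafenib and 71.7% for erlotinib against control. At 1.5-fold the shares were 42.4%, 33.7% and 45.5%. With fewer true changes, or with genes that vary in concert between libraries, the shares may be lower. To see what a shared control group does to the overlap of the drugs, 20 simulations of unchanged groups were run.

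The alternatives tried were DESeq2 1.42.0, RLE normalization, no filter on low counts, leaving out the 20 most abundant genes, fitting only the 2 groups compared, limma on log2 of the authors' scaled signal plus 1, the estimated correlation in camera, and leaving out each library in turn. A model with the atrial marker score as a covariate, and one without Control_1366 and Sunitinib_1370, were added after the data were seen. The labels name no batch or date. The p values measure only the spread between these libraries, since the labels do not say outright that each library is a separate animal.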

Results

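The hearts of mice given 1 of 3 kinase inhibitors for 14 days were compared with those of mice given water, with 3 libraries per group. Sunitinib inhibits the VEGF, PDGF and KIT receptors among others, sorafenib inhibits RAF kinases and VEGF and PDGF receptors, and erlotinib inhibits EGFR. The study's title sets the question as how the drugs change kinases and transcripts in the heart in relation to cardiotoxicity. The control libraries Control_1365, Control_1366 and Control_1367 held 14.4, 14.3 and 16.0 M expected counts (M, 1e+06). The sunitinib libraries Sunitinib_1368, Sunitinib_1369 and Sunitinib_1370 held 16.1, 15.2 and 14.6 M. The sorafenib libraries Sorafenib_1371, Sorafenib_1372 and Sorafenib_1373 held 16.2, 16.5 and 14.5 M, and the erlotinib libraries Erlotinib_1374, Erlotinib_1375 and Erlotinib_1376 held 15.8, 16.1 and 15.8 M. The female-specific transcript Xist had 5934 to 8878 counts in every library, and the 4 Y-linked genes checked had 0. None of the 15 mitochondrially encoded genes looked for was listed.

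In a principal component analysis, erlotinib lay apart from the other drugs. The first component carried 27.9% of the variance, and its scores were 19.8 to 37.4 in the erlotinib libraries, -25.0 to -15.6 in the sunitinib libraries and -10.2 to -3.47 in the sorafenib libraries. Control spread between them, from -13.8 in Control_1365 to 13.2 in Control_1366. In the test of any difference among the 4 groups, 732 of 13440 genes passed in edgeR, with 63 to 1004 when 1 library was left out. The count was 63 without Erlotinib_1376, 126 without Erlotinib_1375, 203 without Sunitinib_1369, 269 without Sorafenib_1373, 273 without Sunitinib_1370 and 372 without Erlotinib_1374. Markers of atrium and conduction tissue differed between libraries within groups. Their score was 0.485 to 0.773 in control, 1.06 and 1.25 in Sunitinib_1368 and Sunitinib_1369 but -1.02 in Sunitinib_1370, 0.770 in Sorafenib_1372 but -1.37 and -1.30 in the other sorafenib libraries, and 0.569, -0.582 and -1.39 in the erlotinib libraries. Of the 55 lists tested, 0 passed in any comparison with an estimated correlation, so the list results rest on the preset correlation of 0.01. Too few members were measured to test T and NK cell (3), B and plasma cell (4), mast cell (2), lung (2) and thymus (2) markers.

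**Figure D1:**
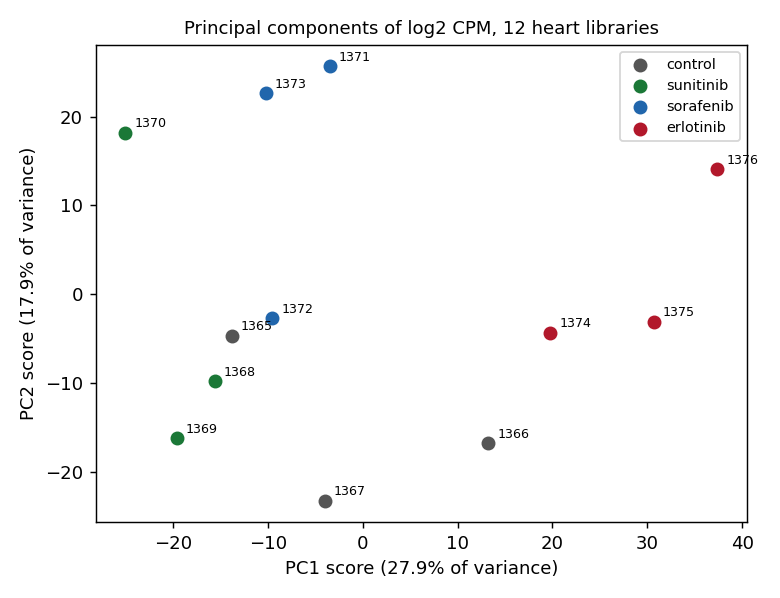
Scores of the 12 heart libraries on the first (PC1) and second (PC2) principal components of log2 CPM, which carried 27.9% and 17.9% of the variance; each point is 1 library, coloured by group and marked with its replicate number. The 3 erlotinib libraries lie at PC1 scores of 19.8 to 37.4 and the 3 sunitinib libraries at -25.0 to -15.6.

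Hearts of mice given sunitinib had lower levels of extracellular matrix genes than control. Of 32 matrix and fibrosis genes measured, 31 had a log2 fold change below 0, and the list fell with a median of -0.48 (camera adjusted p = 3.97e-12; adjusted p = 0.724 with an estimated correlation). Fibrillin 1 (Fbn1, Entrez 14118), which builds microfibrils, was at 38.2 ± 11.1 CPM against 73.1 ± 15.0 in control (n = 3 each; log2 -0.94 ± 0.22, edgeR adjusted p = 0.271). Loxl2, which crosslinks collagen, had a log2 fold change of -1.25 ± 0.33 and Col6a1, a collagen VI chain, one of -0.92 ± 0.25. Adjusted over the list alone, 5 of the 32 genes were lower, and over all genes 0 were. Fibroblast markers fell as well, with 20 of 21 members below 0 and a median of -0.24 (camera adjusted p = 5.95e-06; adjusted p = 0.724 with an estimated correlation). Among them, Col3a1, a fibrillar collagen, had a log2 fold change of -1.13 ± 0.39 and Smoc2, a matricellular protein, one of -0.44 ± 0.07. The matrix score was -1.07 in Sunitinib_1370, which had the low atrial score, against -0.181 and 0.0916 in the other sunitinib libraries and -0.267 to 0.615 in control. Without Sunitinib_1370 the matrix median was -0.30 (camera adjusted p = 3.76e-05) and the fibroblast median -0.15. Without Control_1365 or Sunitinib_1369 the matrix median was -0.74 and the fibroblast median -0.38 or -0.42.

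Proliferation genes fell with a median of -0.45, with 29 of 37 members below 0 (camera adjusted p = 6.83e-05; adjusted p = 0.724 with an estimated correlation). Examples were Kif23, a kinesin of cytokinesis, at -1.17 ± 0.45, and Mcm6, part of the replicative helicase, at -0.67 ± 0.28. Chaperones of the endoplasmic reticulum fell with a median of -0.20, with 20 of 23 below 0 (camera adjusted p = 9.60e-05; adjusted p = 0.724 with an estimated correlation). Adjusted over the list alone, 6 of them were lower, led by the disulfide isomerase Pdia6 at -0.35 ± 0.08 and the chaperone Hsp90b1 at -0.26 ± 0.07. Genes of hypertrophy and the fetal heart program had a median of -0.39 (camera adjusted p = 0.00179; adjusted p = 0.724 with an estimated correlation). Its members included skeletal actin Acta1, at 101 ± 84.2 CPM against 302 ± 59.8, and the stretch-responsive Ankrd1 at -0.39 ± 0.16. Without Sunitinib_1370 that list no longer passed (median -0.20, adjusted p = 0.149), without Control_1367 the medians were -0.29 for Proliferation and -0.10 for Endoplasmic reticulum chaperones, and without Sunitinib_1368 the former was -0.76. Skeletal muscle markers, a list that did not pass, scored -0.464 to -0.302 in the sunitinib libraries against -0.0705 to 0.277 in control. In all, 9 of 55 lists passed camera, 1 higher and 8 lower.

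No single gene passed between sunitinib and control. The edgeR count was 0, with 1460 genes at an unadjusted p under 0.05, while DESeq2 called 86 (50 higher and 36 lower) and limma on the authors' scaled signal called 0. The smallest adjusted p was 0.0914, for the kinase Wnk2 (Entrez 75607), a regulator of ion transport, at 191 ± 19.5 CPM against 127 ± 3.15 (log2 0.59 ± 0.08, edgeR). The endothelin receptor Ednra was at 141 ± 6.87 CPM against 92.9 ± 5.24 (log2 0.60 ± 0.11) and the inward rectifier potassium channel Kcnj2 at 114 ± 7.50 against 88.5 ± 5.43 (log2 0.37 ± 0.07), both with an edgeR adjusted p of 0.203. The same p held for Fhod3, a formin of the sarcomere, at 0.36 ± 0.07, the calcium release channel Itpr2 at 0.46 ± 0.09, the ephrin Efnb3 at 0.46 ± 0.09, the proline oxidase Prodh at 0.51 ± 0.10 and Klhdc8a at -0.72 ± 0.13. Fryl had a log2 fold change of 0.51 ± 0.09 with an adjusted p of 0.175. In 14.6% of genes the 3 sunitinib and 3 control libraries did not overlap, against 10% by chance. That 10% is a mean over all ways to divide these libraries into 3 and 3. Genes that vary in concert can move the share of any 1 division away from it. The shares of other divisions were not computed, so here and below such a share is not read as an excess. Without Control_1365, 12 genes passed, and without Sunitinib_1368, 2 did.

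Hearts of mice given sorafenib had lower levels of macrophage genes than control, and scores of fat markers were lower as well. Of 23 macrophage and monocyte markers, 22 had a log2 fold change below 0, and the list fell with a median of -0.61 (camera adjusted p = 5.25e-16; adjusted p = 0.704 with an estimated correlation). Adjusted over the list alone, 13 members were lower, and over all genes 0 were. Csf1r (Entrez 12978), the receptor for the macrophage growth factor CSF1, was at 28.3 ± 3.18 CPM against 42.5 ± 0.857 in control (n = 3 each; log2 -0.59 ± 0.13, edgeR adjusted p = 0.116). Fcer1g, a signalling chain of Fc receptors, had a log2 fold change of -0.72 ± 0.16 and C1qa, a complement chain made by macrophages, one of -0.66 ± 0.16. White fat markers scored -0.875 to -0.0707 in the sorafenib libraries against 0.260 to 0.553 in control, and brown fat markers -0.390 to -0.154 against 0.120 to 0.358, although neither list passed (camera adjusted p = 0.0671 and 0.599). MHC class II genes fell with a median of -1.18 (camera adjusted p = 0.0137; adjusted p = 0.907 with an estimated correlation), but not without Control_1365 (adjusted p = 0.208), and Liver markers with one of -1.54 (camera adjusted p = 0.00690; adjusted p = 0.907 with an estimated correlation), but not without Control_1367 (adjusted p = 0.0673). The only gene to pass was Retnla (Entrez 57262), a secreted product of alternatively activated macrophages, at 1.82 ± 0.472 CPM against 9.0 ± 1.28, or 4.91-fold lower (log2 -2.30 ± 0.28, edgeR adjusted p = 0.0281). The atrial marker score was lower in 2 of 3 sorafenib libraries than in every control library, and with it as a covariate Retnla had a log2 fold change of -2.06 ± 0.31 (adjusted p = 0.182). Without Control_1365 the edgeR count was 88 and still included Retnla, whereas without Control_1366 or Control_1367 or Sorafenib_1371, Sorafenib_1372 or Sorafenib_1373 it was 0, with Retnla at an adjusted p of up to 0.120.

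Transcripts of ribosomal proteins fell by a small amount with sorafenib, with 45 of 46 below 0 and a median of -0.17 (camera adjusted p = 1.31e-09; adjusted p = 0.907 with an estimated correlation). Control_1366 had a ribosomal score of 0.244, against -0.0338 and -0.0420 in the other control libraries and -0.199 to -0.0536 with sorafenib, and without it the median was -0.07 (adjusted p = 0.0108). Chaperones of the endoplasmic reticulum fell with a median of -0.19 (camera adjusted p = 5.23e-05; adjusted p = 0.907 with an estimated correlation). Adjusted over the list alone, 10 of the 23 were lower, among them Manf at -0.59 ± 0.12 and Pdia6 at -0.37 ± 0.08, and 1 was higher, the oxidase Ero1l (now Ero1a) at 0.38 ± 0.08. Interferon-stimulated genes fell with a median of -0.52 and 31 of 32 below 0 (camera adjusted p = 2.00e-04; adjusted p = 0.907 with an estimated correlation), examples being Ifi27l2a at -0.80 ± 0.29 and Rtp4 at -0.62 ± 0.30. Endothelial markers rose with a median of 0.12 (camera adjusted p = 0.00242; adjusted p = 0.907 with an estimated correlation), and 8 of 28 were higher adjusted over the list alone. Egfl7, an angiogenic factor made by endothelium, was at 101 ± 2.20 CPM against 73.6 ± 5.12 (log2 0.46 ± 0.08, edgeR adjusted p = 0.0721), and Fabp4, a fatty acid carrier of capillary endothelium, had a log2 fold change of 0.47 ± 0.12. Matrix genes and fibroblast markers also fell, with medians of -0.28 and -0.27 (camera adjusted p = 0.00388 and 0.00334; adjusted p = 0.917 and 0.907 with an estimated correlation). Neither passed without Control_1367 (medians -0.07 and -0.09, adjusted p = 0.216 and 0.0504) or Sorafenib_1371 (medians -0.12 and -0.21, adjusted p = 0.152 and 0.0639), and the matrix median was -0.43 without Control_1365 and -0.44 without Sorafenib_1372. Without Control_1365 the interferon (median -0.34, adjusted p = 0.173) and endothelial (median 0.03, adjusted p = 0.201) lists no longer passed, and the endothelial median was 0.28 without Control_1366 and 0.07 without Control_1367. In all, 14 lists passed camera, 3 higher and 11 lower.

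Genes just short of the threshold with sorafenib had an edgeR adjusted p of 0.0549. Higher in the means were the secreted kinase Pkdcc, at 60.9 ± 8.70 CPM against 30.2 ± 3.43 (log2 1.01 ± 0.14), Mctp1 at 1.38 ± 0.21, Ednra at 146 ± 20.3 CPM against 92.9 ± 5.24 (log2 0.66 ± 0.11), the endothelial adhesion receptor Eltd1 (now Adgrl4) at 0.50 ± 0.08 and the phosphate exporter Xpr1 at 0.39 ± 0.06. Lower in the means were apolipoprotein E (Apoe), at 299 ± 21.6 CPM against 524 ± 97.4 (log2 -0.81 ± 0.13), the iron carrier transferrin (Trf) at -0.89 ± 0.14, the elastic fibre protein Fbln5 at -0.76 ± 0.12 and Mlf1 at -0.55 ± 0.09. At an unadjusted p under 0.05 there were 1667 genes, and DESeq2 called 175 (88 higher and 87 lower) and limma on the authors' scaled signal 4. The share of genes without overlap was 16.3%, against 10% by chance.

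Immediate early genes rose with erlotinib; they are the transcription factors and messenger RNA regulators that cells induce within minutes of a stimulus. All 18 measured had a log2 fold change above 0, with a median of 1.22 (camera adjusted p = 1.54e-12; adjusted p = 0.182 with an estimated correlation), and 7 were higher adjusted over the list alone. Junb, an AP-1 subunit, had a log2 fold change of 0.93 ± 0.19 (edgeR adjusted p = 0.0639), Btg2, an antiproliferative gene, one of 1.22 ± 0.28 and Zfp36, which destabilises cytokine messenger RNAs, one of 1.21 ± 0.31, none of which passed over all genes. Arc (Entrez 11838), an activity-induced gene best known from neurons, rose from 2.52 ± 0.917 to 12.8 ± 1.47 CPM, or 5.09-fold (n = 3 each; log2 2.35 ± 0.37, edgeR adjusted p = 0.0385). Spry4 (Entrez 24066), a feedback inhibitor of receptor tyrosine kinase to ERK signalling, rose 2.59-fold, from 14.1 ± 1.03 to 36.5 ± 7.99 CPM (log2 1.37 ± 0.15, edgeR adjusted p = 0.00642). The ERK feedback list as a whole had 11 of 17 members above 0 and a median of 0.14 (camera adjusted p = 0.00447; adjusted p = 0.182 with an estimated correlation), and a median of 0.03 without Erlotinib_1375. The members that passed over all genes were Spry4 and Epha2, an ephrin receptor, at 15.8 ± 0.262 CPM against 8.88 ± 1.16 (log2 0.83 ± 0.13), while Etv1, an ETS factor, was lower adjusted over the list alone, at -0.54 ± 0.16. Spry4 did not pass without Control_1365 or Control_1367, and Arc and Epha2 passed in 1 of the 6 fits that left out a library, that without Control_1366.

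Heat shock genes rose with erlotinib, with 22 of 23 above 0 and a median of 0.23 (camera adjusted p = 2.57e-09; adjusted p = 0.182 with an estimated correlation). Of them, 6 were higher adjusted over the list alone and 1 over all genes, the small heat shock protein Hspb1 (Entrez 15507), at 423 ± 35.4 CPM against 259 ± 13.9 (log2 0.71 ± 0.11, edgeR adjusted p = 0.0385). Hspb1 passed in 2 of the 6 fits that left out a library, and in neither of those without Control_1365 or Control_1367. The cytosolic chaperones Hsp90aa1 and Hspa8 had log2 fold changes of 0.47 ± 0.09 (edgeR adjusted p = 0.0537) and 0.37 ± 0.09 (adjusted p = 0.0790). Glucocorticoid targets rose with all 22 above 0 and a median of 0.62 (camera adjusted p = 2.62e-06; adjusted p = 0.553 with an estimated correlation), and none passed singly, either over the list alone or over all genes. Control_1366 had a glucocorticoid score of 0.576, above those of Erlotinib_1374 and Erlotinib_1375 (0.502 and 0.547), and without it the median was 1.01. Errfi1, a feedback inhibitor of EGFR that glucocorticoids also induce, had a log2 fold change of 1.30 ± 0.36, Cebpd one of 1.04 ± 0.39 and the clock gene Per1 one of 0.42 ± 0.17. Inflammation and NF-kB genes rose with 22 of 26 above 0 and a median of 0.57 (camera adjusted p = 2.42e-04; adjusted p = 0.392 with an estimated correlation). Examples were Ptgs2, an inducible cyclooxygenase, at 1.25 ± 0.38, and Nfkb2 at 0.37 ± 0.10. The score of this list was 1.04 in Erlotinib_1375 against 0.246 and 0.455 in Erlotinib_1374 and Erlotinib_1376, and without Erlotinib_1375 the median was 0.26 (adjusted p = 0.0221). Neutrophil markers scored 1.49 and 1.80 in Erlotinib_1375 and Erlotinib_1376, -0.146 in Erlotinib_1374 and -0.966 to 0.582 in control. Endothelial markers rose with a median of 0.18 (camera adjusted p = 4.03e-04; adjusted p = 0.522 with an estimated correlation), for example the junction protein Esam at 0.68 ± 0.13 and the guidance receptor Robo4 at 0.49 ± 0.09, with a list median of 0.09 without Erlotinib_1376 and a highest adjusted p of 0.0123, without Control_1365. Markers of fibroblasts and of atrium fell, with medians of -0.25 and -0.62 (both camera adjusted p = 0.00160; adjusted p = 0.573 and 0.553 with an estimated correlation). With the atrial score as a covariate, Immediate early genes had a median of 1.21 (adjusted p = 1.95e-12) and Heat shock genes one of 0.19 (adjusted p = 8.24e-08), and the fibroblast list no longer passed (median -0.06, adjusted p = 0.27).

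**Figure D2:**
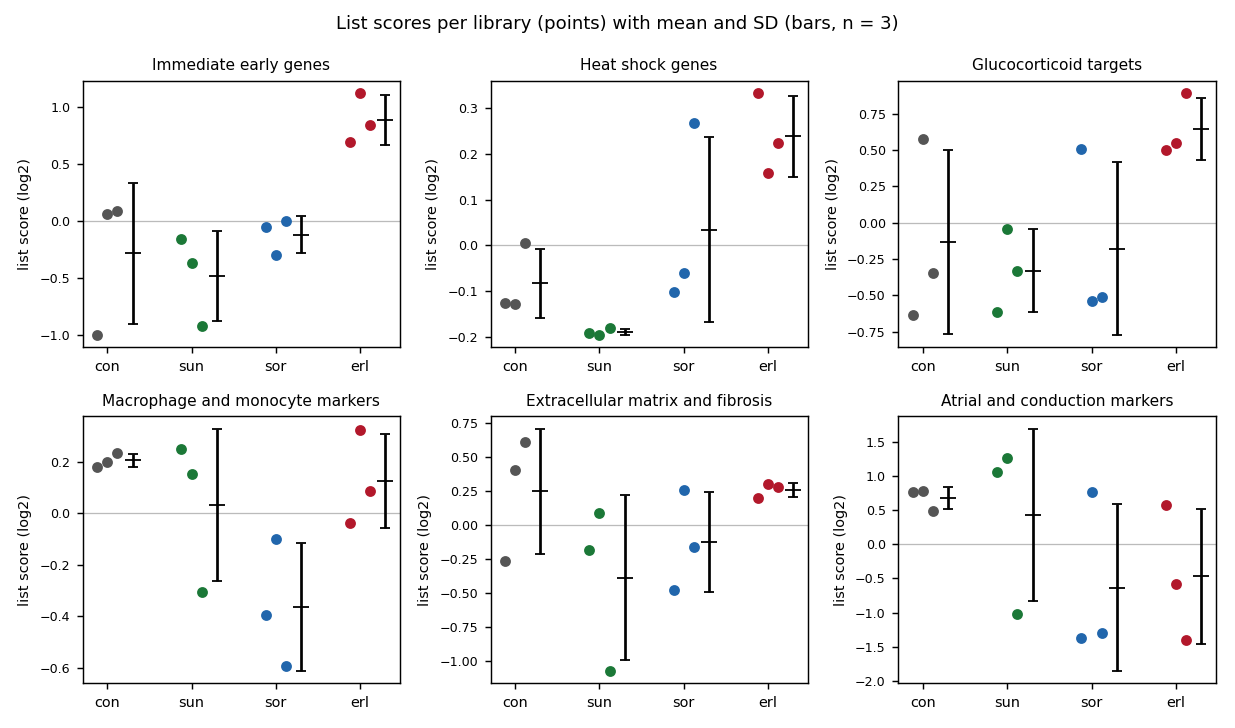
Scores of 6 gene lists (mean log2 CPM of the members relative to all 12 libraries) in control (con), sunitinib (sun), sorafenib (sor) and erlotinib (erl) hearts; points are libraries and bars are the mean and SD (n = 3). Immediate early genes score 0.694 to 1.12 in the erlotinib libraries and at most 0.0879 in the others, and macrophage markers score -0.593 to -0.101 in the sorafenib libraries against 0.181 to 0.234 in control.

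In all, 39 genes passed between erlotinib and control, 23 higher and 16 lower, with a median absolute log2 fold change of 0.628. The aryl hydrocarbon receptor target Cyp1a1 (Entrez 13076), a cytochrome P450 that oxidises aromatic compounds, had 104 summed counts with erlotinib (28 to 48 per library) and 2 in control (0 to 1 per library), a ratio of 50.9 (exact binomial 95% interval 13.8 to 426, for counting error only; edgeR adjusted p = 0.00993). It averaged under 1 CPM over the 12 libraries, so it fell outside the rule and was chosen after its values were seen. The receptor's target list had a median of 0.21 (camera adjusted p = 0.0491; adjusted p = 0.553 with an estimated correlation), and did not pass without Control_1365 (adjusted p = 0.149), Control_1367 (0.104), Erlotinib_1374 (0.0537) or Erlotinib_1375 (0.0754). Also higher were the elongation factor Ell2 at 0.83 ± 0.11, the pseudokinase Trib1 at 0.82 ± 0.15, the phosphodiesterase Pde4c at 0.63 ± 0.11, the co-chaperone Dnajb5 at 0.57 ± 0.10 and the scaffold Shank3 at 0.56 ± 0.10. The water channel Aqp4 (Entrez 11829) fell 5.33-fold, from 14.1 ± 5.0 to 2.63 ± 0.397 CPM (log2 -2.41 ± 0.40, edgeR adjusted p = 0.0447). The potassium channels Kcnj2 and Kcnh2, which carry repolarising currents of the heart, fell by 0.47 ± 0.07 and 0.59 ± 0.11 on the log2 scale (edgeR adjusted p = 0.0385 and 0.0447). Other falls were those of Aff3 (-1.38 ± 0.24), Klhl33 (-0.94 ± 0.18), Lonrf2 (-0.82 ± 0.13), the red cell membrane protein Gypc (-0.78 ± 0.12), the agrin receptor Lrp4 (-0.77 ± 0.13), Plcl2 (-0.75 ± 0.13), Lrrc15 (-0.74 ± 0.13), Nhsl1 (-0.73 ± 0.12) and the glutathione transferase Gstt1 (-0.68 ± 0.12). The list of red cell transcripts moved the other way from Gypc, with a mean score of 0.182 with erlotinib against -0.169 in control. The erlotinib calls depended on single libraries. Without Control_1365 or Control_1367 the count was 0, without Control_1366 it was 236, and without Erlotinib_1374, Erlotinib_1375 or Erlotinib_1376 it was 22, 3 or 2, with Spry4 between an adjusted p of 0.00153 and 0.0847 over these 6 fits. With the atrial score as a covariate 0 genes passed, with Spry4 at 1.35 ± 0.17 (adjusted p = 0.0616), Arc at 2.37 ± 0.44 (adjusted p = 0.108) and Aqp4 at -2.64 ± 0.43 (adjusted p = 0.0985), so the folds stayed close and the p values rose. At an unadjusted p under 0.05 there were 2090 genes, and 20.6% of genes had no overlap, against 10% by chance. DESeq2 called 363, of which 37 were among the 39. Limma on the authors' scaled signal called 15 higher and 34 lower, so the share of higher genes was 30.6% there and 59.0% in edgeR. The median log2 fold change of all tested genes was -0.0592 there and -0.00764 in edgeR, so that scaling moved the whole comparison down. Of 55 lists, 23 passed camera, 16 higher and 7 lower.

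**Figure D3:**
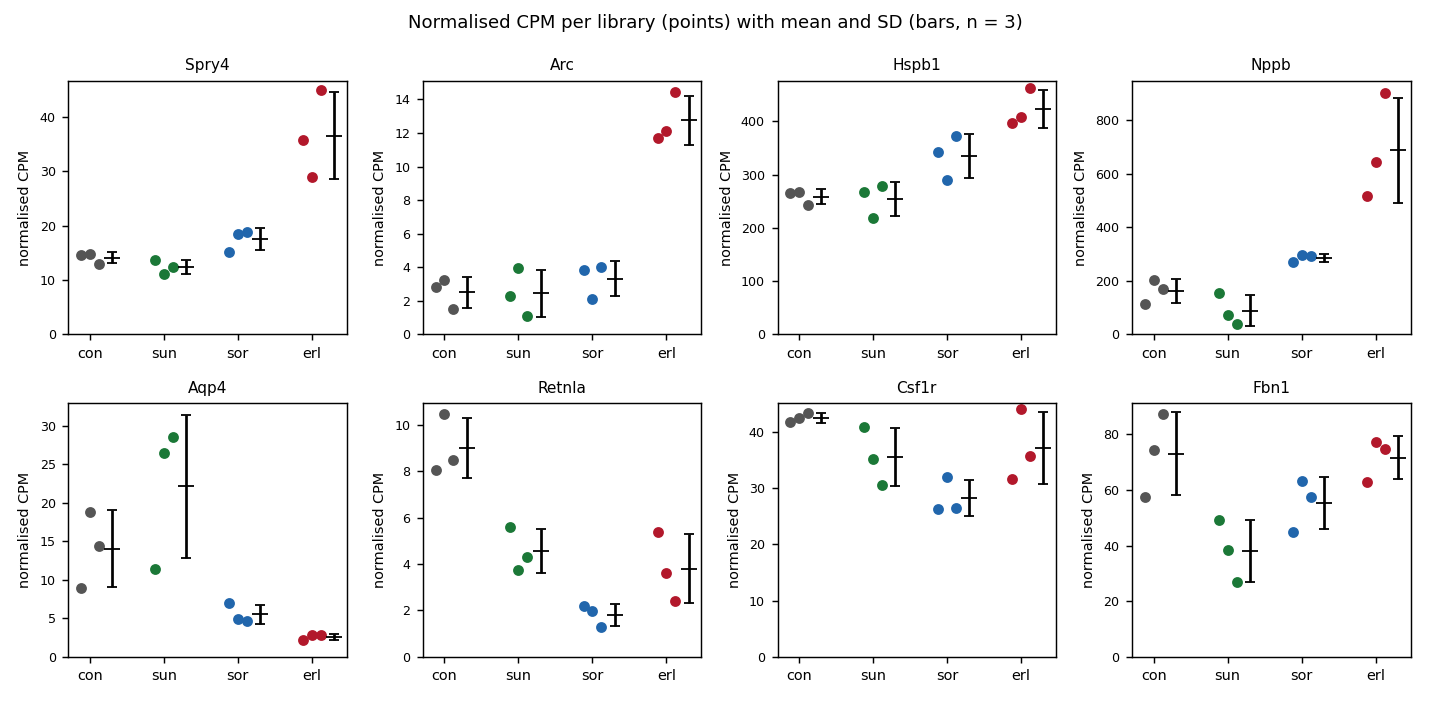
Normalised CPM of 8 genes in the 12 heart libraries, by group; points are libraries and bars are the mean and SD (n = 3). Spry4 lies at 29.0 to 44.9 CPM in the erlotinib libraries and at 18.9 or less in the others, and Retnla at 1.29 to 2.20 CPM in the sorafenib libraries against 8.06 to 10.5 in control.

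None of the drug targets and cardiac stress genes fixed for every comparison passed against control. Egfr itself, the target of erlotinib, had a log2 fold change of -0.24 with erlotinib (95% interval -0.85 to 0.36, edgeR adjusted p = 0.728), and Erbb2 and Erbb4 had ones of -0.28 ± 0.16 and -0.25 ± 0.17. The VEGF receptor Kdr was at 222 ± 26.4 CPM with sorafenib against 129 ± 58.5 in control (log2 0.78 ± 0.31, edgeR adjusted p = 0.351), and had a log2 fold change of 0.36 ± 0.31 with sunitinib. Leaving out 1 library took these to between 0.49 and 1.14 with sorafenib and between 0.06 and 0.71 with sunitinib. The stem cell factor receptor Kit was at 2.18 ± 0.392 CPM with sunitinib against 4.11 ± 0.939 (log2 -0.91, 95% interval -1.50 to -0.32, edgeR adjusted p = 0.301). The PDGF receptor Pdgfra had log2 fold changes of -0.20 ± 0.11, -0.30 ± 0.11 and -0.45 ± 0.11 with sunitinib, sorafenib and erlotinib, and Pdgfrb ones of 0.05 ± 0.10, 0.23 ± 0.10 and -0.09 ± 0.10. For STAT signalling, Stat3 had log2 fold changes of -0.07 ± 0.13, 0.05 ± 0.13 and 0.17 ± 0.13 and its target Socs3 ones of -0.39 ± 0.56, -0.63 ± 0.57 and 1.52 ± 0.54 in the same order. With erlotinib, Socs3 ran from 0.86 to 2.23 when 1 library was left out. The list of STAT3 and STAT5 targets rose with erlotinib (median 0.41, camera adjusted p = 0.00590; adjusted p = 0.553 with an estimated correlation), but not without Control_1365 (adjusted p = 0.0624), and with a median of 0.19 without Erlotinib_1375. Nppb (Entrez 18158), the natriuretic peptide of ventricular wall stress, was at 687 ± 197 CPM with erlotinib against 163 ± 45.1 (log2 2.07, 95% interval 1.05 to 3.10, edgeR adjusted p = 0.0924; DESeq2 adjusted p = 0.00116). It was at 88.8 ± 59.0 CPM with sunitinib and 286 ± 15.1 with sorafenib. The list of hypertrophy and fetal cardiac genes as a whole rose with erlotinib, with 14 of 16 above 0, a median of 0.20 and 4 higher adjusted over the list alone (camera adjusted p = 4.44e-04; adjusted p = 0.522 with an estimated correlation). Its median was 0.31 without Control_1367, 0.34 without Erlotinib_1374 and 0.12 without Erlotinib_1376. The myosin heavy chains Myh6 and Myh7 had log2 fold changes between 0.03 and 0.15 with all 3 drugs, with SE of 0.07 and 0.08. The atrial peptide Nppa was not determined, with log2 fold changes of -0.00 ± 0.65, 0.18 ± 0.65 and 0.09 ± 0.65 with sunitinib, sorafenib and erlotinib. For sorafenib it was -0.51 without Sorafenib_1372 and 0.57 without Control_1366.

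Between sunitinib and sorafenib, which share receptor targets, lists of cell types, ribosomal proteins, heat shock and heart muscle genes differed. Macrophage markers were higher with sunitinib, with 21 of 23 above 0 and a median of 0.43 (camera adjusted p = 1.41e-08; adjusted p = 0.430 with an estimated correlation). Ribosomal proteins were higher by a small amount, with 44 of 46 above 0 and a median of 0.13 (camera adjusted p = 4.53e-06; adjusted p = 0.741 with an estimated correlation). Calcium handling and ion channel genes were higher with a median of 0.17 (camera adjusted p = 4.23e-05; adjusted p = 0.430 with an estimated correlation), and Kcnj2 passed singly, at 114 ± 7.50 CPM against 81.9 ± 3.27 (log2 0.48 ± 0.07, edgeR adjusted p = 0.0478). Endothelial markers were lower, with 25 of 28 below 0 and a median of -0.22 (camera adjusted p = 4.53e-06; adjusted p = 0.430 with an estimated correlation), as were heat shock genes, with a median of -0.17 (camera adjusted p = 1.44e-05; adjusted p = 0.430 with an estimated correlation). Atrial markers were higher with a median of 0.70 (camera adjusted p = 1.23e-05; adjusted p = 0.430 with an estimated correlation), following the library differences given above. Medians were 0.28 for macrophage markers without Sunitinib_1368, 0.08 for Calcium handling and ion channels and 0.08 for Ribosomal proteins without Sunitinib_1370, and -0.07 for Heat shock genes and 0.08 for Ribosomal proteins without Sorafenib_1373. Of the 5 genes that passed, all higher with sunitinib, the ephrin Efnb3 (Entrez 13643) had the smallest adjusted p, at 155 ± 22.0 CPM against 92.2 ± 1.71 (log2 0.75 ± 0.09, edgeR adjusted p = 0.0118). The others were Lrp4 at 0.85 ± 0.13, the desmosomal cadherin Dsg2 at 0.52 ± 0.08, Pdzd2 at 0.52 ± 0.07 and Kcnj2. At an unadjusted p under 0.05 there were 1325 genes, 14.6% of genes had no overlap, against 10% by chance, and DESeq2 called 139, among them all 5. The edgeR count was 0 without any 1 of the 3 sorafenib libraries and with only these groups fitted, 1 without Sunitinib_1370, 2 without Sunitinib_1369 and 37 without Sunitinib_1368.

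Sunitinib and erlotinib differed in more genes than either drug did from control. Heat shock genes were lower with sunitinib in 23 of 23 members, with a median of -0.23 (camera adjusted p = 2.79e-09; adjusted p = 0.339 with an estimated correlation). Of them, 9 passed over all genes, led by Dnajb4 at -1.0 ± 0.12, Hsp90aa1 at -0.67 ± 0.09 and Hspb1 at -0.73 ± 0.11. Immediate early genes were lower with a median of -1.27 (camera adjusted p = 3.99e-09; adjusted p = 0.339 with an estimated correlation), and 7 passed, among them Junb at -1.14 ± 0.19 and Zfp36 at -1.75 ± 0.31. Genes of hypertrophy were lower with a median of -0.72 (camera adjusted p = 3.25e-06; adjusted p = 0.339 with an estimated correlation), including Nppb, at 88.8 ± 59.0 CPM with sunitinib against 687 ± 197 with erlotinib (log2 -2.95 ± 0.47, edgeR adjusted p = 0.00790), and Ankrd1 at -1.15 ± 0.16. Nppb had an adjusted p of 0.0530 with only these groups fitted, and the median of the hypertrophy list was -0.44 without Sunitinib_1370. Atrial and conduction markers were higher with sunitinib, with a median of 0.91 and 5 of 16 passing over all genes (camera adjusted p = 4.83e-04; adjusted p = 0.406 with an estimated correlation). A difference in the share of atrial tissue can therefore enter this comparison. Of 31 genes of calcium handling and ion channels, 8 were higher with sunitinib and 1 lower, against 853 and 742 of all 13440 genes. Kcnj2 was at 114 ± 7.50 CPM against 63.8 ± 3.34 (log2 0.84 ± 0.07, edgeR adjusted p = 3.18e-04), Kcnh2 had a log2 difference of 0.82 ± 0.11, and the potassium channel Kcna5 was the lower one, at -1.39 ± 0.18. The list itself did not pass (camera adjusted p = 0.0653).

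Glucocorticoid targets were lower with sunitinib than with erlotinib, with a median of -0.79 (camera adjusted p = 4.66e-06; adjusted p = 0.495 with an estimated correlation), for example Errfi1 at -2.17 ± 0.37. Spry4 was at 12.4 ± 1.32 CPM against 36.5 ± 7.99 (log2 -1.56 ± 0.15, edgeR adjusted p = 3.18e-04). Cyp1a1 had 1 count over the sunitinib libraries against 104, a ratio of 0.00965 (exact binomial 95% interval 0.000242 to 0.0550, counting error only; edgeR adjusted p = 8.28e-04). Among genes that passed, averaged at least 1 CPM over the 12 libraries and had no overlap, gene models aside, the largest differences toward sunitinib were in Aqp4, at 22.2 ± 9.31 CPM against 2.63 ± 0.397 (log2 3.07 ± 0.39), the transcription factor Tox at 3.00 ± 0.57, the Wnt antagonist Sfrp5 at 2.96 ± 0.80, Ubxn10 at 2.57 ± 0.43 and the methyltransferase Inmt at 2.44 ± 0.34. Under the same limits, which leave out Cyp1a1, the largest toward erlotinib were in the stress factor Atf3, at 6.03 ± 2.93 CPM against 105 ± 93.8 (log2 -4.11 ± 0.98), Cytip, which regulates adhesion of leukocytes, at 0.696 ± 0.247 against 9.52 ± 1.59 (log2 -3.76 ± 0.51), the matrix glycoprotein Thbs1 at -3.63 ± 0.83, the neutrophil collagenase Mmp8 at -3.27 ± 0.93 and the transcription factor Runx3 at -3.04 ± 0.76. Neutrophil and granulocyte markers were lower with sunitinib, with a median of -1.62 (camera adjusted p = 0.0124; adjusted p = 0.632 with an estimated correlation), but not without Erlotinib_1376 (adjusted p = 0.0588). Erlotinib_1374 scored within the range of the sunitinib libraries. In all, 1595 genes passed in edgeR, 853 higher with sunitinib and 742 lower, and 33.7% of genes had no overlap, against 10% by chance. Limma on the authors' scaled signal called 1164 higher and 549 lower, a higher share of 68.0% against 53.5% in edgeR. The median log2 difference of all tested genes was 0.0567 there and 0.00744 in edgeR. The count was 783, 798, 832 and 404 without Sunitinib_1369, Sunitinib_1370, Erlotinib_1375 and Erlotinib_1376. Atf3, Thbs1, Mmp8 and Runx3 passed in 1 of the 6 fits that left out a library, the one without Erlotinib_1374. Sfrp5 did likewise.

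Between sorafenib and erlotinib, chaperones of the endoplasmic reticulum were lower with sorafenib, with 19 of 23 below 0 and a median of -0.29 (camera adjusted p = 1.69e-08; adjusted p = 0.462 with an estimated correlation). Of them, 6 passed over all genes, such as Manf at -0.68 ± 0.12 and calreticulin (Calr) at -0.41 ± 0.07. Macrophage markers were lower with a median of -0.52 (camera adjusted p = 9.58e-08; adjusted p = 0.462 with an estimated correlation), 4 of them over all genes, such as Tyrobp, a signalling adaptor of myeloid cells, at -0.63 ± 0.14. Neutrophil and granulocyte markers were lower with a median of -1.69 (camera adjusted p = 7.54e-04; adjusted p = 0.680 with an estimated correlation), none of them over all genes. The scores of this list overlapped, at -1.21 to 0.677 in the sorafenib libraries and -0.146 to 1.80 in the erlotinib libraries. Immediate early genes were lower with a median of -1.02 (camera adjusted p = 9.58e-08; adjusted p = 0.462 with an estimated correlation), and Junb passed at -1.11 ± 0.19. Spry4 was at 17.6 ± 2.02 CPM against 36.5 ± 7.99 (log2 -1.06 ± 0.15, edgeR adjusted p = 0.00873), and Cyp1a1 had 1 count over the sorafenib libraries against 104 (edgeR adjusted p = 0.00626). Higher with sorafenib were Hhex, a homeobox factor of endothelium, at 2.03 ± 0.27, Rassf9 at 18.5 ± 0.764 CPM against 5.01 ± 0.617, Atcay at 2.73 ± 0.48, the transcription factor Sox9 at 2.10 ± 0.47 and the methylcytosine dioxygenase Tet1 at 1.99 ± 0.42. Lower were Cytip at -3.60 ± 0.50, the endotoxin co-receptor Cd14 at -2.68 ± 0.58, the stress gene Gadd45b at -2.55 ± 0.51 and the paralogs Serpina3i and Serpina3h at -2.87 ± 0.43 and -2.72 ± 0.42, between which reads are hard to assign. In all, 363 genes passed in edgeR, 210 higher with sorafenib and 153 lower, DESeq2 called 828 that included all 363, and 25.2% of genes had no overlap, against 10% by chance. Limma on the authors' scaled signal called 302 higher and 139 lower, a higher share of 68.5% against 57.9%. The median log2 difference of all tested genes was 0.0345 there and 0.000393 in edgeR. The count was 1 without Erlotinib_1376, which was Cyp1a1 and not Spry4, Hhex or Rassf9, 19 without Erlotinib_1375, 12 without Sorafenib_1373, 50 without Sorafenib_1372, 78 without Sorafenib_1371 and 190 without Erlotinib_1374. Sox9, Cd14, Gadd45b and Tyrobp passed in none of these fits.

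With 1 gene called for sorafenib against control and none for sunitinib, calls shared between drugs cannot be read from edgeR, while DESeq2 gave 21 for sunitinib and sorafenib, 3 for sunitinib and erlotinib and 24 for sorafenib and erlotinib. How many the shared controls alone would give in DESeq2 was not simulated. These counts are therefore not read as an effect in common. The fold changes against control had a covariance across genes of 0.0513 for sunitinib and sorafenib, against 0.0352 in the simulations, where only the shared controls link the drugs. For sorafenib and erlotinib it was 0.0397 against 0.0352, and for sunitinib and erlotinib -0.00257 against 0.0348. Without Control_1366 the value for sunitinib and sorafenib was 0.0508 against 0.0533, without Control_1367 it was 0.0618 against 0.0567 and without Control_1365 0.0886 against 0.0550. For sorafenib and erlotinib it was 0.0430 against 0.0568 without Control_1367, and 0.0610 against 0.0547 and 0.0642 against 0.0540 without Control_1365 and Control_1366, so for both pairs the sign of the difference rested on the control libraries used. For sunitinib and erlotinib it was below the simulated value in all 3, at 0.0179 against 0.0543, 0.0211 against 0.0537 and 0.00694 against 0.0566 without Control_1365, Control_1366 and Control_1367. Genes are not independent replicates, and the 3 controls cannot be divided between the drugs, so part of each covariance comes from the shared controls. Without Control_1365 the pair of sunitinib and sorafenib shared 7 genes in edgeR, also without a simulated count.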

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

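The models with the atrial score and without Control_1366 and Sunitinib_1370 were chosen after the results were seen. Where a value moved, the cause was not tested unless given. DESeq2 called more genes: 86 for sunitinib, 175 for sorafenib and 363 for erlotinib against control, 139 for sunitinib against sorafenib, 828 for sorafenib against erlotinib and 1663 for any difference, with 21, 3 and 24 shared between sunitinib and sorafenib, sunitinib and erlotinib, and sorafenib and erlotinib. With no filter on low counts, the counts were 1 (Wnk2) for sunitinib, 20 for sorafenib and 9 for sunitinib against sorafenib, 1 call was shared by sorafenib and erlotinib, and the covariances rose to 0.372, 0.290 and 0.390 in the order given, since genes near 0 have wide fold changes. With only the groups compared, 0 genes passed for sunitinib against sorafenib and 686 for sorafenib against erlotinib. For erlotinib against control 28 passed, of which only 16 were among the 39. Limma on the authors' scaled signal called 4 for sorafenib against control and 3 for sunitinib against sorafenib. With an estimated correlation, 0 lists passed in each of the 6 comparisons. With the atrial score, 1 gene passed for sunitinib (Wnk2), 0 for sorafenib, 0 for erlotinib and 2 for sunitinib against sorafenib, 338 for any difference, and 8 lists for sorafenib and 11 for erlotinib. Without Control_1366 and Sunitinib_1370, 0 genes passed for sorafenib, 241 for erlotinib (37 of the 39 among them), 1 for sunitinib against sorafenib and 988 for sunitinib against erlotinib. The median of Oxidative phosphorylation, nuclear-encoded was then 0.01 for sorafenib (0.00715) and -0.04 for sunitinib against sorafenib (-0.0359), both reversed. Leaving out 1 library at a time gave 0 to 12 genes and 10 to 21 lists for sunitinib, 0 to 88 genes for sorafenib, 0 to 236 genes and 15 to 26 lists for erlotinib, 0 to 37 genes and 13 to 20 lists for sunitinib against sorafenib, 404 to 1314 genes for sunitinib against erlotinib, 1 to 190 for sorafenib against erlotinib and 63 to 1004 for genes, any difference among the 4 groups. Shared calls of sunitinib and sorafenib ran from 0 to 7, and the values of fold change covariance, sunitinib and sorafenib from 0.0598 to 0.104, of fold change covariance, sunitinib and erlotinib from 0.00964 to 0.0285 and of fold change covariance, sorafenib and erlotinib from 0.0469 to 0.0791, over genes filtered anew in each fit. A mean over fewer controls carries more noise into both drugs. Reversed among these fits were Oxidative phosphorylation, nuclear-encoded (-0.127 to 0.00719 for sorafenib, reversed without Control_1366; -0.0310 to 0.104 for sunitinib against sorafenib, reversed without Sunitinib_1370), Interferon-stimulated genes (-0.115 to 0.613 for sunitinib against sorafenib) and Antigen presentation, MHC class II (-0.0914 to 1.62), both without Sunitinib_1368. Among named genes, those that passed here or in the alternative kept their sign, whereas some that passed in neither did not, such as Socs3 for sorafenib (-0.94 to 0.08), and RLE normalization or leaving out the 20 most abundant genes kept all 39 erlotinib calls. Genes of 1.5-fold change were recovered in 33.7% to 45.5% of simulated cases, and no smaller change was simulated.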

Other observations

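The genes in this paragraph were chosen after their values were seen, and the tests of a single library, of the time of day, of Control_1366 and of opposite changes in the later paragraphs were also chosen after the results were seen. Several genes moved alike with sunitinib and sorafenib, though none passed over all genes against control. The clock repressor Nr1d1 was at 53.3 ± 17.9 CPM with sunitinib and 57.2 ± 4.81 with sorafenib, against 125 ± 28.6 in control (n = 3 each; log2 -1.22 ± 0.22 and -1.12 ± 0.22, edgeR adjusted p = 0.203 and 0.114). With erlotinib its log2 fold change was 0.03 ± 0.22. The clock gene Per2 was at 56.3 ± 4.41 and 59.7 ± 3.64 CPM against 39.5 ± 5.62 (log2 0.51 ± 0.11 and 0.60 ± 0.11, edgeR adjusted p = 0.234 and 0.0770), with 0.23 ± 0.11 for erlotinib. Socs2, a feedback inhibitor of growth hormone signalling through STAT5, was at 23.0 ± 3.65 and 24.1 ± 2.63 CPM against 35.7 ± 5.88 (log2 -0.63 ± 0.14 and -0.57 ± 0.13, edgeR adjusted p = 0.234 and 0.137), with 0.07 ± 0.13 for erlotinib. The glucose transporter Slc2a1 was at 24.6 ± 3.45 and 24.4 ± 1.99 CPM against 18.0 ± 1.19 (log2 0.45 ± 0.11 and 0.44 ± 0.11, edgeR adjusted p = 0.259 and 0.146), with 0.09 ± 0.11 for erlotinib. Neuregulin 1 (Nrg1), a ligand of the ErbB receptors made by cardiac endothelium, had log2 fold changes of 1.38 ± 0.39, 1.5 ± 0.38 and 1.51 ± 0.38 with sunitinib, sorafenib and erlotinib (edgeR adjusted p = 0.286, 0.157 and 0.0997). Part of what the drugs have in common comes from the shared control libraries. Nr1d1 and Per2 are clock genes and the labels give no time of collection, so a different hour of collection stays open for them. Between sorafenib and erlotinib, which were compared without the controls, Nr1d1 passed at -1.15 ± 0.22 and Socs2 at -0.63 ± 0.13 (edgeR adjusted p = 0.0326 for both), but neither passed in any of the 6 fits that left out a library of these groups (adjusted p of 0.0630 to 0.133 for Nr1d1 and 0.0731 to 0.139 for Socs2). Between sunitinib and erlotinib, also compared without the controls, Nr1d1 passed at -1.25 ± 0.22 and Socs2 at -0.70 ± 0.13 (edgeR adjusted p = 0.00894 and 0.00830), and both passed in all 6 such fits (highest adjusted p 0.0424 and 0.0453). Slc2a1 passed at 0.36 ± 0.11 between sunitinib and erlotinib (edgeR adjusted p = 0.0456), but in only 1 of these fits, and not between sorafenib and erlotinib (adjusted p = 0.0990). Per2 passed in neither comparison (adjusted p = 0.114 for sunitinib and 0.0918 for sorafenib), nor did Nrg1, at -0.13 ± 0.33 and -0.00 ± 0.33.

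With erlotinib, hypoxia genes rose with a median of 0.09 (camera adjusted p = 4.74e-04; adjusted p = 0.182 with an estimated correlation), among them the prolyl hydroxylase P4ha1 at 0.50 ± 0.11, and the median was 0.22 without Control_1365 and 0.15 without Erlotinib_1376. Neutrophil markers rose with 7 of 8 above 0 and a median of 1.39 (camera adjusted p = 0.00569; adjusted p = 0.573 with an estimated correlation), but not without Erlotinib_1376 (median 0.90, adjusted p = 0.0635). The list for the arm of the clock that holds the Per genes and Dbp fell with a median of -0.36 (camera adjusted p = 0.0105; adjusted p = 0.573 with an estimated correlation), but not without Control_1365 (median -0.20, adjusted p = 0.149). Per1 and Per2 themselves went the other way. Their log2 fold changes with erlotinib were 0.32 to 0.49 and 0.14 to 0.34 over the fits that left out 1 library, and neither passed. The ErbB list did not pass (camera adjusted p = 0.774), although 3 of its members were higher adjusted over the list alone, namely Nrg1, the EGFR ligand Hbegf, at 61.1 ± 14.2 CPM against 30.8 ± 6.15, and Errfi1. Its median of -0.14 and mean of 0.08 differed in sign.

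Of 100 splits of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many genes with any difference as the real 732. Such a count was thus rare among these splits, which cannot give a share under 1 in 100. The highest other, 586, kept the sunitinib and erlotinib libraries whole and mixed control with sorafenib. Splits of 3 against 3 number 10, so no share can be under 0.1. For genes called, the real count and the highest other were 0 and 1 for sunitinib against control (10 splits as large, the real one included), 1 and 2 for sorafenib (3 splits), 39 and 0 for erlotinib (1 split), 5 and 23 for sunitinib against sorafenib (2 splits), 1595 and 0 for sunitinib against erlotinib (1 split), and 363 and 0 for sorafenib against erlotinib (1 split). For lists, in the same order, they were 9 and 25 (10 splits), 14 and 24 (4 splits), 23 and 20 (1 split), 20 and 23 (5 splits), 14 and 23 (8 splits), and 16 and 19 (3 splits). Other splits thus passed more lists than the real one in 5 of 6 comparisons, which points to members of a list varying in concert between libraries of 1 group. By list, up to 6 of the 10 splits gave a p as small as the real one in a comparison with control (oxidative phosphorylation with sorafenib). As further examples, 4 splits gave a p as small as the real one for Inflammation and NF-kB genes with erlotinib and for Ribosomal proteins and matrix genes with sorafenib, 3 for matrix, fibroblast and Proliferation lists with sunitinib and for fibroblast markers with erlotinib, and 2 for chaperones of the endoplasmic reticulum with sunitinib, for hypertrophy genes with sunitinib and erlotinib and for fibroblast markers with sorafenib, against 1 for macrophage markers with sorafenib. Between drugs, all 10 splits gave a p as small for interferon-stimulated genes with sunitinib against sorafenib and with sorafenib against erlotinib. The same held for MHC class II genes with sunitinib against sorafenib. For macrophage markers 3 splits did so in each of these comparisons, as did 3 for Ribosomal proteins with sunitinib against sorafenib. For immediate early genes 1 did, with sunitinib and with sorafenib against erlotinib. For sunitinib against sorafenib another split called 23 genes against 5, which points to a structure of the samples that was not tested further.

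Immediate early, heat shock and glucocorticoid genes were higher with erlotinib. A single library as the whole source is excluded for immediate early and heat shock genes. With the preset correlation, the highest camera adjusted p over the fits that left out 1 library was 5.02e-09 (without Control_1365) and 4.51e-06 (without Control_1366). For Glucocorticoid targets it was 8.45e-04 (without Control_1365), which cannot exclude a single library. Another split of the same libraries gave this list a camera p of 5.38e-12, against 1.43e-07 for the real one. Glucocorticoid targets were less secure, since 4 of the 10 splits gave a p as small, against 1 for each of the other lists, Control_1366 scored above 2 of the 3 erlotinib libraries, and their median ran from 0.42 to 1.01 over these fits. The time of day at which hearts were collected stays open, since the labels give none and within groups the immediate early score and that of the Per and Dbp arm of the clock had a Pearson r of -0.337 (exact permutation p = 0.535 over 1296 orders; Spearman rho -0.175, permutation p = 0.684; r = -0.170 without Control_1365 and Sunitinib_1368), in 12 libraries and 1 relation computed, too few to decide. Handling of the animals before collection could also induce these genes and was not tested, so an effect of erlotinib is a hypothesis.

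Macrophage markers were lower with sorafenib, and so were the scores of fat markers. A single library is excluded as the source. Over the fits that left out 1 library the median stayed at -0.712 to -0.527 (highest camera adjusted p 1.24e-10, without Sorafenib_1373, with the preset correlation). A different share of atrial tissue, as far as the atrial score measures it, is excluded as the whole cause. With that score as a covariate the median was -0.45 (camera adjusted p = 1.59e-09, with the preset correlation) against -0.61. A part of the fall may still come from it. Gene length and expression level are excluded, since 0 of 10000 random lists matched on both had a median as low (median of these -0.03, lowest -0.25). Less fat tissue in the sorafenib hearts stays open, since white fat markers had a mean score of -0.454 against 0.426 in control and brown fat markers one of -0.268 against 0.257, and fewer macrophages or a lower output of these transcripts per cell may also give this pattern.

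Sunitinib and erlotinib differed in 1595 genes, more than either drug differed from control in. Whether Control_1366 was the reason for the low counts against control stays open. Without it, 236 genes passed for erlotinib against control, up from 39, and 0 passed for sunitinib, as before. These fits had fewer libraries than the fit that gave 1595, so the counts cannot be compared directly. Fits of sunitinib against erlotinib that also left out a library gave 404 to 1314 genes, above both counts. A different share of atrial tissue, as far as the atrial score measures it, is excluded as the whole cause, since 1111 genes passed with that score as a covariate. Shares of other tissues were not fitted and stay open. Skeletal muscle markers, a list that did not pass, scored -0.464 to -0.302 in the sunitinib libraries and 0.0977 to 0.433 in the erlotinib libraries. The candidate explanation that the drugs move genes in opposite directions from control went with the covariance of their fold changes, which was 0.0373 under that of simulated unchanged groups (difference -0.0373). The simulated genes vary independently whereas real libraries vary in concert, so the simulated spread is too small to test that difference. Nor is the covariance separate evidence, since for changes of a given size against control, a lower covariance means a larger difference between the drugs. The explanation stays a hypothesis.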
